A study of Bos taurus with 6 samples.

How the data were processed

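Gene expression was measured by RNA sequencing in 6 libraries of BEND cells, an established bovine endometrial epithelial line, 3 transfected with a miR-200b mimic and 3 with a negative-control mimic. Per the labels' protocols, cells grew in DMEM with fetal bovine serum, RNA was extracted with TRIzol and libraries were made with Illumina's stranded TruSeq mRNA kit, which selects polyadenylated RNA. The labels give no dose and no time after transfection. Groups and replicate numbers were taken from the sample titles.

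The authors deposited 1 table of raw counts per gene and library, with gene identifiers, symbols and annotation terms per the file headers. Trimmomatic, HISAT2 and HTSeq are named in the submitters' processing notes, without versions or roles. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no genomic coordinates are printed. The table held 20958 genes, of which 5579 had a count of 0 in all 6 libraries. In it 26 symbols were stored as dates, and all 26 were restored through their GeneID. A RefSeq gene table (assembly ARS-UCD2.0) held the GeneIDs of 97.8% of the genes, and served for current names, for genes that overlap a neighbour and for genomic span. No mitochondrially encoded gene was in the table, so that list of RNA quality genes had 0 tested members.

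Library totals ranged from 19212694 to 21129547 counts. CPM values were computed from these counts with TMM-scaled library sizes (factors of 0.983 to 1.01). Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12217 genes and at least 99.96% of each library's counts. The common dispersion was 0.00516, a biological coefficient of variation of 7.18%. The first principal component of log2 CPM held 51% of the variance and separated the groups, and the next held 17%. Where a gene had 1 to 3 reads over the NC libraries, the ratio of summed counts is given with an exact 95% interval, and where it had 0 a floor of 3 counts over the group was used. Intervals and floors cover counting error only.

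The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, robust dispersion, the group as the single factor and Benjamini-Hochberg adjustment at 0.05, two-sided. Standard errors are the log2 fold change divided by the square root of F. Tested on simulated counts of 12152 genes with 200 changed genes, the test recovered 68% of genes changed by 0.5 on the log2 scale, 89.8% at 1 and 100% at 2 and at 3. In that simulation 9.69% of the calls were false, more than the 0.05 set by the adjustment. Its genes were drawn independently, without drift shared between genes, so these rates may not hold for the real libraries.

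Gene lists were written from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for named genes. The lists covered literature targets of miR-200b, epithelial junctions and keratins, the mesenchymal state, matrix, integrins, actin regulators, TGF-beta and BMP signalling, pro- and anti-apoptotic genes, p53 targets, cell cycle phases, interferon, NF-kB, prostaglandin and receptivity, PI3K-AKT, MAPK, Hippo and Wnt, stress responses, trafficking, lipid synthesis, glycolysis, oxidative phosphorylation, chromatin, small RNA pathway, autophagy, markers of 5 other cell types and RNA quality genes. Lists with at least 5 tested members, 29 in all, were tested with limma's camera (preset correlation 0.01, prior count 2, two-sided, Benjamini-Hochberg over lists), with camera under an estimated correlation and with fry beside it. Fry tests whether the genes of a list move on balance in 1 direction, without comparing them with other genes. Annotation terms with 10 to 500 tested genes were tested with a one-sided Fisher's exact test, separately for higher and lower genes.

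The text names the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 1, an ordinary symbol and no overlap between the groups' values, up to 4 members of each list with the smallest p, and a set of genes fixed in advance (ZEB1, ZEB2, CDH1, EPCAM, VIM, BCL2, BAX, MKI67, ESRP1, QKI and FN1, among others). Some genes that this rule selects are not reported here. Other genes are named to complete a group and were chosen after their values were seen: KRT7, PKP2, OVOL2, PPM1F, CFL2, FLT1, THBS2, ACVR1, WNT5A, MET, ENG, CD14, MYB, the complement genes and the examples of genes nearly absent from the NC libraries. COL1A1, COL1A2, THY1, KRT8 and KRT19 were also chosen after their values were seen, and are named only for their NC level. Between 3 and 3 libraries, a single gene's groups separate without overlap in 10% of cases by chance.

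Alternatives were other scalings (RLE and upper quartile), no filter and a stricter one (CPM of at least 1 in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, minimum fold changes and term sizes of 20 to 300. A test of miR-200b seed sites in 3' untranslated regions, with its alternatives, was planned but needs a genome sequence and was not analysed here.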

Results

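RNA sequencing was carried out on BEND cells, an established line of bovine endometrial epithelial cells, after transfection with a mimic of the bovine microRNA miR-200b or with a negative-control mimic, here called NC. A mimic is a synthetic RNA duplex that supplies the cell with the mature microRNA. The series held 6 libraries, 3 per group. Total gene counts were 21129547, 20313320 and 20281474 in mimic replicates 1 to 3, and 20253017, 20146963 and 19212694 in NC replicates 1 to 3. Between 14029 and 14155 genes had at least 1 read in a library, and the 10 most abundant genes took 6.25% to 6.81% of the counts. The mature microRNA is not captured by an mRNA library, so its own level was not analysed here. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 5.13 to 11.9. Pairs across the groups had 8.55 to 22.1, so the ranges overlapped, and mimic replicate 3 differed less from NC replicate 3, at 8.55, than from mimic replicate 1, at 11.9.

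The comparison of mimic with NC asks which transcripts change when miR-200b is overexpressed in endometrial epithelial cells. Several genes known from epithelia were among the largest rises. CRB3, an apical polarity protein of epithelia, rose from 0.388 ± 0.159 to 18.3 ± 1.77 CPM (read counts scaled to library size; mean ± SD, n = 3 per group). TNS4, a tensin of focal adhesions, rose from 0.565 ± 0.317 to 28.3 ± 5.85 CPM. CDH1, which encodes E-cadherin, rose 3.24-fold, from 11.3 ± 0.912 to 36.5 ± 2.29 CPM, and the simple-epithelium keratin KRT18 rose 1.94-fold, from 541 ± 11.3 to 1048 ± 74.2 CPM. ZEB1, the zinc finger repressor of E-cadherin and a well-known miR-200b target, fell by 27.1%, from 40.2 ± 2.16 to 29.3 ± 3.13 CPM.

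By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 525 of 12217 tested genes were higher and 263 were lower in the mimic libraries at an adjusted p under 0.05. The median log2 fold change was 0.47 among the higher genes and −0.38 among the lower ones. Of the higher genes, 101 had a log2 fold change of at least 1, against 13 of the lower genes. Of these large changes, 92 of the 101 rises and 11 of the 13 falls started from an NC mean under 10 CPM. A limit of the counts was their dependence on single libraries. Without mimic replicate 2 the test called 322 higher and 82 lower genes, and without NC replicate 1 it called 275 and 93. The lower genes numbered 414 without mimic replicate 3 and 153 without NC replicate 3.

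**Figure D1:**
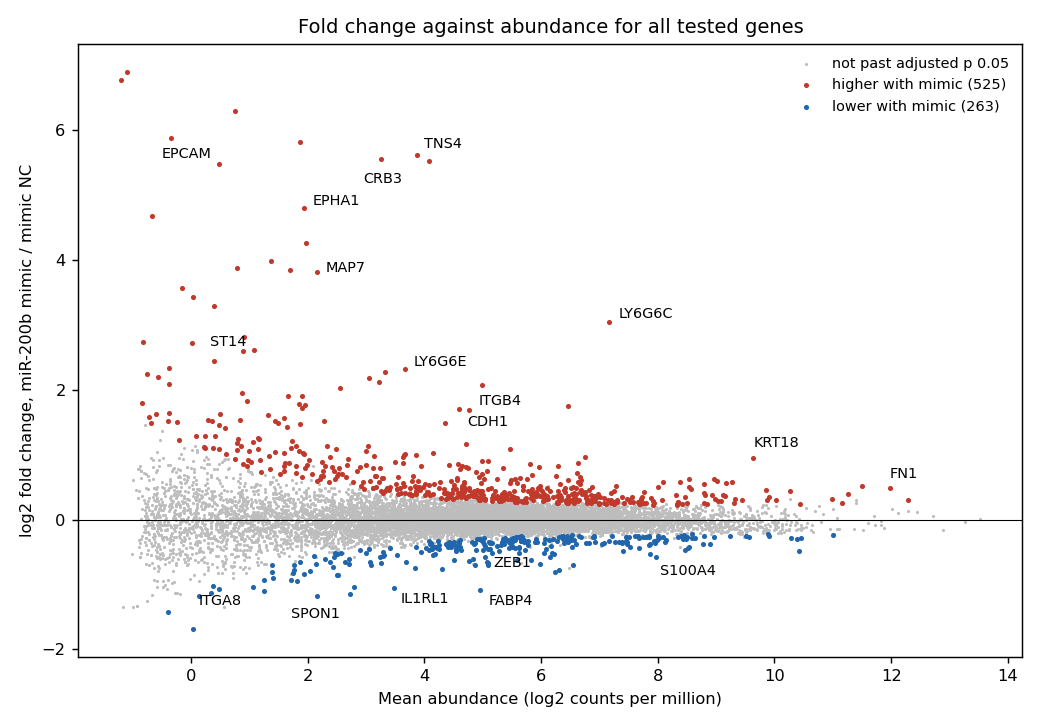
Fold change of each tested gene (log2, mimic over NC) against its mean abundance (log2 CPM), with 1 point per gene. Red points are the 525 genes called higher with mimic, blue points are the 263 called lower and grey points are the rest, and the largest rises lie among genes of low abundance.

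The 12 largest rises among genes above the abundance minimum included several genes known from epithelia. The log2 fold changes were 5.62 ± 0.24 (SE) for TNS4 and 5.55 ± 0.21 for CRB3. EPHA1, an ephrin receptor, rose by 4.79 ± 0.27 and AP1M2, the epithelial subunit of a clathrin adaptor for basolateral sorting, by 4.26 ± 0.27. EPS8L1, which binds actin regulators, rose by 3.99 ± 0.31, the B-box protein BSPRY by 3.84 ± 0.27 and the microtubule-binding MAP7 by 3.81 ± 0.23. LY6G6C, a lipid-anchored surface protein, was the most abundant of these, at 256 ± 13.7 CPM against 31.1 ± 1.46. ST14, the membrane protease matriptase, rose by 2.62 ± 0.29, and LY6G6E, a relative of LY6G6C, by 2.31 ± 0.13. All 12 had an adjusted p of 1.63e-06 or less in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CRB3 and LY6G6C overlap neighbouring genes, DENND1C and MPIG6B, and the strand setting of the counting is not given in the sources used here, so reads of the neighbours could not be told apart.

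The largest falls were smaller. SPON1, a matrix-associated spondin, fell from 6.06 ± 0.826 to 2.68 ± 0.588 CPM, a log2 change of −1.18 ± 0.19. EEF1A2, a translation elongation factor, changed by −1.15 ± 0.17 and PLEKHG4, a guanine nucleotide exchange factor, by −1.11 ± 0.22. IL1RL1, the receptor of interleukin-33, fell from 14.9 ± 0.591 to 7.18 ± 0.341 CPM. FABP4, a fatty acid binding protein, changed by −1.09 ± 0.24, the integrin chain ITGA8 by −1.04 ± 0.25 and GFRA2, a receptor of neurturin, by −1.04 ± 0.17. The remaining 5 of the 12 were S100A1 at −0.95, PECAM1 at −0.93, ANG at −0.93, CDH18 at −0.90 and TNFRSF11B, the decoy receptor osteoprotegerin, at −0.86. PLEKHG4, IL1RL1, PECAM1, ANG and TNFRSF11B overlap neighbours, ANG with RNASE4, and their values are uncertain to that extent. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p rose to 0.0852 for FABP4 without mimic replicate 1, to 0.0742 for S100A1 and 0.115 for PECAM1 without mimic replicate 2, and to 0.146 for ITGA8 and 0.135 for CDH18 without NC replicate 1. FABP4 also lost its call without a filter on low counts, at an edgeR adjusted p of 0.146.

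Of 23 tested members of the epithelial junction and keratin list, 15 rose, none fell and 8 did not pass. Adjusted over the list alone, 18 were higher and 0 lower. CDH1 had a log2 fold change of 1.70 ± 0.10, the tight junction scaffold PATJ 0.97 ± 0.08, KRT18 0.95 ± 0.07 and the desmosomal plakophilin PKP2 0.85 ± 0.09. KRT7, a keratin of simple glandular epithelia, rose from 0.215 ± 0.204 to 2.19 ± 0.364 CPM. EPCAM, an epithelial adhesion molecule, had 155 reads over the mimic libraries and 3 over the NC libraries, a depth-adjusted ratio of 50.1 with an exact 95% interval of 16.8 to 246 that covers counting error only. OVOL2, a transcription factor that represses ZEB1, had 41 reads against 0, at least 13.3-fold higher when 3 reads over the group are taken as the floor. ESRP1, an epithelial splicing regulator, had 12 reads against 0 and was too low to test. The list median was 0.51, also with OVOL2 at its bound, and the camera set test gave an adjusted p of 1.02e-20. This was the single list of 29 still called with an estimated correlation, at an adjusted p = 0.0419 with an estimated correlation. PATJ overlaps an uncharacterised locus. Markers of fibroblast or stromal cells had a list median of −0.21 and ribosomal protein genes of −0.15 in the same libraries, each at an adjusted p = 0.401 with an estimated correlation.

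**Figure D2:**
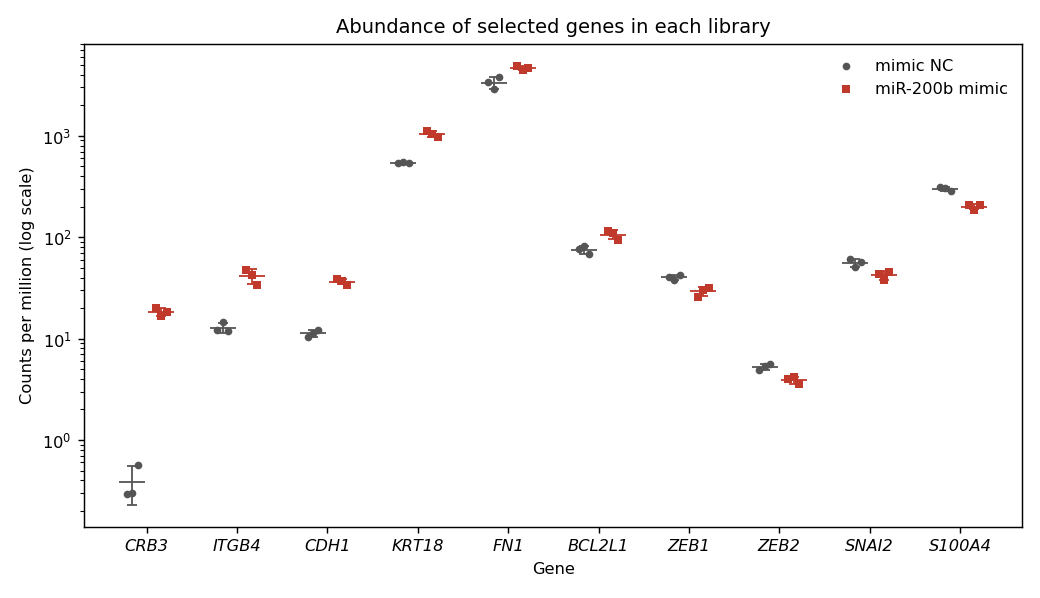
Abundance of 10 genes in CPM on a log axis, with 1 point per library, grey for NC and red for mimic, and horizontal bars for the mean with error bars of 1 SD (n = 3). CRB3 and ITGB4 had means of 0.388 and 12.9 CPM in NC and of 18.3 and 41.4 CPM with mimic, while ZEB1, SNAI2 and S100A4 were lower with mimic, and ZEB2 did not pass the adjusted threshold.

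Several genes of the mesenchymal state were lower with the mimic, by small amounts. Of 26 tested mesenchymal genes, 7 fell, 1 rose and 18 did not pass, and adjusted over the list alone 9 were lower and 1 higher. S100A4, a calcium-binding protein of motile mesenchymal cells, fell by 33.2%, the matrix glycoprotein TNC by 30.1% and SNAI2, the E-cadherin repressor Slug, by 25.1%. VIM, which encodes the intermediate filament vimentin, stood at 3587 ± 173 CPM against 3942 ± 205, with an adjusted p of 0.29 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Over the mesenchymal list the median was −0.13 and the camera adjusted p was 0.000399, with an adjusted p = 0.316 with an estimated correlation. In edgeR's quasi-likelihood test, SNAI2 lost its call without mimic replicate 2, at an adjusted p of 0.0642, and without NC replicate 1. The fibroblast or stromal markers, 2 of which are also in the mesenchymal list, had a median of −0.21 in the same libraries.

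Targets of miR-200b known from the literature were not called as a set. Of 28 tested, 5 fell, 2 rose and 21 did not pass, against 9 lower and 4 higher adjusted over the list alone. ZEB1 had a log2 fold change of −0.46 ± 0.09 and an adjusted p of 0.0025 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. ZEB2, the other ZEB repressor of E-cadherin, stood at −0.44 ± 0.16 with an edgeR adjusted p of 0.12, and QKI, an RNA-binding splicing factor, at −0.21 ± 0.07 with an edgeR adjusted p of 0.094. SEC23A, a coat component of vesicles leaving the endoplasmic reticulum, fell by 21.7%, the angiogenic factor VEGFA by 21.6%, the phosphatase PPM1F by 0.31 on the log2 scale and CFL2, an actin-severing cofilin, by 0.28. FN1, the gene of fibronectin, rose 1.4-fold, from 3353 ± 435 to 4679 ± 216 CPM, and FLT1, a VEGF receptor, rose from 14 ± 0.904 to 18.1 ± 2.05 CPM. PPM1F, CFL2 and FLT1 were added to the named genes after their values were seen. Over the target list the median was −0.04, with a camera adjusted p of 0.0526, which became 0.0243 without mimic replicate 2 and 0.0425 without NC replicate 1. The edgeR adjusted p rose to 0.0528 for VEGFA without NC replicate 3, to 0.0989 for PPM1F and 0.249 for FLT1 without mimic replicate 2, and to 0.152 for CFL2 without mimic replicate 1. Each of PPM1F, FLT1 and CFL2 also lost its call without NC replicate 1 and without NC replicate 3, and FLT1 with upper quartile scaling, DESeq2 and limma-voom. SEC23A and ZEB2 overlap uncharacterised loci.

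Several integrin chains, matrix genes and actin regulators rose. Of 28 tested integrin and focal adhesion genes, 8 rose, none fell and 20 did not pass, and 14 were higher adjusted over the list alone. ITGB4, a laminin receptor chain of hemidesmosomes, rose 3.22-fold, from 12.9 ± 1.4 to 41.4 ± 6.95 CPM. The collagen receptor chain ITGA2 rose 2.03-fold and the laminin receptor chain ITGA3 rose 1.51-fold. ITGB6, an epithelial integrin chain, had 62 reads against 2, a ratio with an exact 95% interval of 7.97 to 254. The integrin list had a median of 0.19 and the camera adjusted p 7.57e-05, against an adjusted p = 0.401 with an estimated correlation. Of 31 tested matrix genes, 6 rose, 2 fell and 23 did not pass, and adjusted over the list alone 7 were higher and 4 lower. LAMB3, a laminin beta chain of epithelial basement membranes, had a log2 fold change of 3.57 ± 0.49, and THBS1, a matricellular thrombospondin, 0.58 ± 0.08. The small proteoglycan DCN fell by 0.42 ± 0.08 on the log2 scale and THBS2 by 0.37 ± 0.10. The matrix list was not called by camera, at an adjusted p of 0.333. Of 32 tested actin regulators, 7 rose, 1 fell and 24 did not pass, the same counts as those adjusted over the list alone. CNN2, a calponin, rose 1.55-fold and MYH10, a non-muscle myosin heavy chain, 1.43-fold, and CFL2 was the lower one. The actin list had a camera adjusted p of 0.0778 and a fry adjusted p of 0.0149. THBS2 was named after its values were seen, and its edgeR adjusted p was 0.258 without mimic replicate 2, while that of CFL2 was 0.152 without mimic replicate 1. Both also lost their calls without NC replicate 1 and without NC replicate 3. THBS1, ITGA2 and MYH10 overlap neighbours, FSIP1, MOCS2 and NDEL1. Stromal markers, 6 of which are also in the matrix list, had a list median of −0.21 in the same libraries.

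The labels tie the experiment to apoptosis, and genes of the apoptotic machinery showed few differences. None of 29 tested pro-apoptotic genes passed, over all genes or adjusted over the list alone, and the list median was −0.07 with a camera adjusted p of 0.208. BAX, which permeabilises mitochondria, had a log2 fold change of −0.08 ± 0.08, with an edgeR adjusted p of 0.65. HTRA2, a mitochondrial protease that binds apoptosis inhibitors, stood at −0.27 ± 0.09 with an edgeR adjusted p of 0.061. Of 15 tested anti-apoptotic genes 1 rose, or 2 adjusted over the list alone, and the list had a camera adjusted p of 0.134. The gene that rose was BCL2L1, which encodes the survival protein Bcl-xL, from 75.3 ± 7.25 to 106 ± 11 CPM, with an edgeR adjusted p of 0.00056. BCL2 was scarce, at 1.01 ± 0.0906 CPM against 0.669 ± 0.113, and had an edgeR adjusted p of 0.37. BAX overlaps TULP2 and HTRA2 overlaps LOXL3.

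Among 24 tested p53 targets, 4 rose, none fell and 20 did not pass, with 5 higher adjusted over the list alone. PLK2, a stress-induced polo-like kinase, rose 1.52-fold. GADD45A, a DNA damage-inducible growth arrest gene, rose 1.21-fold, PHLDA3, an Akt inhibitor, 1.21-fold and MDM2, the ubiquitin ligase of p53, 1.19-fold. The p53 list had a median of 0.06 and a camera adjusted p of 0.0364, with an adjusted p = 0.401 with an estimated correlation. Camera's adjusted p was 0.108 without mimic replicate 3, 0.0628 without NC replicate 2, 0.0751 without NC replicate 3 and 0.0548 with the replicate block. In edgeR's test the adjusted p rose to 0.0885 for GADD45A and 0.246 for MDM2 without mimic replicate 2, and to 0.206 for PHLDA3 without NC replicate 1. All 3 also lost their calls without NC replicate 3, and MDM2 with upper quartile scaling and limma-voom.

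The medians of the cell cycle lists were slightly above 0, with small or no separation of the libraries by group. All 33 tested genes of the G2/M and mitosis list had a log2 fold change above 0, 9 rose, none fell and 24 did not pass, and 14 were higher adjusted over the list alone. MKI67, the proliferation marker Ki-67, rose 1.33-fold, from 381 ± 29.1 to 505 ± 40.1 CPM, and the kinetochore protein CENPF rose 1.33-fold. The list median was 0.21 and the camera adjusted p 2.28e-08, with an adjusted p = 0.401 with an estimated correlation. Of 34 tested G1/S and replication genes, 4 rose, none fell and 30 did not pass, with 5 higher adjusted over the list alone. CDK6, a kinase of G1 progression, rose 1.36-fold, its partner cyclin D1, CCND1, rose 1.34-fold, and MCM10 and POLE, both of the replication machinery, rose 1.25-fold and 1.24-fold. That list had a median of 0.16 and a camera adjusted p of 0.000399, with an adjusted p = 0.448 with an estimated correlation. For its mean log2 level, centred over the 6 libraries, the groups overlapped, with mimic replicate 3 at −0.0731 and NC replicate 2 at 0.0433. For the G2/M list the closest libraries were mimic replicate 3 at 0.0136 and NC replicate 2 at 0.00535. Ribosomal protein genes, included as a sign of RNA quality, moved the other way in the same libraries. None of the 33 tested ribosomal protein genes had a log2 fold change above 0, and 2 fell, RPS23 by 16.8% and RPL12 by 15.4%, against 8 lower adjusted over the list alone. Their median was −0.15 and the camera adjusted p 2.28e-08, with an adjusted p = 0.401 with an estimated correlation. Ribosomal protein genes have many near-identical copies, so these values are uncertain. CCND1 and RPS23 overlap ORAOV1 and ATG10. In edgeR's test, RPS23, RPL12, MCM10 and POLE lost their calls both without mimic replicate 2 and without NC replicate 1. Their highest adjusted p was 0.261 for RPL12 and 0.367 for MCM10 without mimic replicate 2, and 0.273 for RPS23 and 0.346 for POLE without NC replicate 1, in edgeR's test. MCM10 and POLE also lost their calls with upper quartile scaling and limma-voom.

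Receptor and growth signalling genes changed in both directions. Of 31 tested PI3K-AKT and receptor tyrosine kinase genes, 4 rose, 3 fell and 24 did not pass, and adjusted over the list alone 6 were higher and 3 lower. ERBB3, a neuregulin receptor, rose 2.3-fold, the catalytic subunit PIK3CB 1.37-fold, the regulatory subunit PIK3R1 1.3-fold and the hepatocyte growth factor receptor MET 1.19-fold. PIK3R3, another regulatory subunit, fell by 31% and the platelet-derived growth factor receptors PDGFRB and PDGFRA fell by 20.9% and 16.6%. This list had a median of 0.09 with a camera adjusted p of 0.024, and an adjusted p = 0.401 with an estimated correlation. Of 30 tested Hippo-YAP and Wnt genes, 6 rose, none fell and 24 did not pass, and adjusted over the list alone 6 were higher and 1 lower. CTGF and CYR61, matricellular proteins and classical YAP targets, rose 1.37-fold and 1.3-fold, and ANKRD1, another YAP target, 1.28-fold. The list median was 0.08 with a camera adjusted p of 0.0145, and an adjusted p = 0.401 with an estimated correlation. Of 31 tested MAPK feedback and immediate early genes, 3 rose and 28 did not pass, also when adjusted over the list alone. They were DUSP6, an ERK phosphatase, and the transcription factors EGR2 and ATF3, with log2 fold changes of 0.36 ± 0.09, 0.83 ± 0.25 and 0.27 ± 0.08. The MAPK list had a median of 0.11 with a camera adjusted p of 0.0147, and an adjusted p = 0.401 with an estimated correlation. Camera's adjusted p for the PI3K list was 0.0951 without mimic replicate 3 and 0.217 without NC replicate 2, for the Hippo list 0.112 without NC replicate 2 and for the MAPK list 0.0715 without mimic replicate 1. The edgeR adjusted p rose to 0.151 for MET, 0.163 for PDGFRB and 0.12 for DUSP6 without mimic replicate 2, to 0.173 for PDGFRA and 0.199 for ATF3 without NC replicate 1, and to 0.142 for EGR2 without NC replicate 3. EGR2 lost its call without each of the 6 libraries in turn and with DESeq2 and limma-voom, and ATF3 with both other scalings and limma-voom. MET was named after its values were seen.

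Single genes of TGF-beta, interferon, inflammatory and prostaglandin signalling changed, and camera called none of these lists. Of 30 tested TGF-beta and BMP genes, 3 rose and 2 fell, also when adjusted over the list alone, and the list median was 0.02 with a camera adjusted p of 0.756. GREM1, a secreted BMP antagonist, fell by 37.4% and the receptor ACVR1 by 0.28 on the log2 scale, while TGFB2 rose 1.35-fold, the activin antagonist FST 1.23-fold and LTBP2, of the latent TGF-beta binding protein family, 1.24-fold. Of 22 tested interferon-stimulated genes 1 rose, or 2 adjusted over the list alone, and the list had a camera adjusted p of 0.966. The gene that rose was IRF7, a transcription factor of the type I interferon response, 1.55-fold. HERC5, an ISG15 ligase, stood at 0.36 ± 0.11 with an edgeR adjusted p of 0.056. Of 25 tested NF-kB and cytokine genes 1 rose, also when adjusted over the list alone, and it was LIF, a cytokine of embryo implantation, 1.54-fold higher. The camera adjusted p of that list was 0.48, and its median of −0.01 and its mean of 0.05 differed in sign. Of 22 tested prostaglandin and receptivity genes, 3 rose and 2 fell, also when adjusted over the list alone, with a median of 0.04, a camera adjusted p of 0.327 and a fry adjusted p of 0.0076. PTGER4, a prostaglandin E2 receptor, rose 1.68-fold, the adhesive glycoprotein SPP1 1.35-fold and the protease CTSL 1.33-fold, while PTGES, a prostaglandin E synthase, fell by 21.3% and the ligand WNT5A by 0.24 on the log2 scale. The edgeR adjusted p rose to 0.31 for ACVR1, 0.0606 for FST, 0.255 for LTBP2 and 0.249 for WNT5A without NC replicate 1, to 0.0625 for PTGER4 and 0.237 for PTGES without mimic replicate 2, and to 0.13 for SPP1 without mimic replicate 1. WNT5A lost its call without each of the 6 libraries in turn, and ACVR1 with limma-voom. ACVR1 and WNT5A were named after their values were seen.

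The medians of metabolic and stress lists were slightly under 0, with few single genes past the threshold. None of 35 tested nuclear oxidative phosphorylation genes passed, over all genes or adjusted over the list alone, and 2 had a log2 fold change above 0. COX6A1, a cytochrome c oxidase subunit, stood at −0.19 ± 0.07 with an edgeR adjusted p of 0.096, and the list median was −0.12 with a camera adjusted p of 2.77e-05. That call was lost, at an adjusted p = 0.401 with an estimated correlation. In centred mean log2 level of the list the groups overlapped, with mimic replicate 1 at −0.0136 and NC replicate 3 at −0.0329. Of 30 tested autophagy and lysosome genes 1 fell, also when adjusted over the list alone, the protease CTSB by 17.1%, and the list median was −0.12 with a camera adjusted p of 0.00311. It too had an adjusted p = 0.401 with an estimated correlation, and its groups overlapped, with mimic replicate 3 at 0.00197 and NC replicate 2 at −0.00291. Of 31 tested genes of the unfolded protein and integrated stress response, 2 fell, also when adjusted over the list alone. They were the lipoprotein receptor VLDLR, by 26.2%, and PSAT1, a serine synthesis enzyme, by 20.6%, and the list median was −0.07 with a camera adjusted p of 0.0303. This list had an adjusted p = 0.401 with an estimated correlation, and camera gave 0.0715 without mimic replicate 1, 0.066 without mimic replicate 2 and 0.0534 without NC replicate 1. Of 31 tested glycolysis and hypoxia genes, 2 rose and 2 fell, also when adjusted over the list alone. The glucose transporter SLC2A1 rose 1.89-fold and the enolase ENO1 1.2-fold, while EPAS1, a hypoxia-inducible factor, fell by 20.5% and the stress-responsive NDRG1 by 16.7%. The list median was −0.08 with a camera adjusted p of 0.0386, and an adjusted p = 0.401 with an estimated correlation. Camera gave this list 0.0545 under a stricter filter on low counts, 0.156 without mimic replicate 3, 0.0982 without NC replicate 2 and 0.0748 without NC replicate 3. Ribosomal protein genes had a median of −0.15 in the same libraries. Without NC replicate 1, edgeR no longer called CTSB, VLDLR, PSAT1, SLC2A1, ENO1, EPAS1 and NDRG1, with an adjusted p of 0.175 for CTSB, 0.0625 for VLDLR and 0.215 for ENO1. Without mimic replicate 2, edgeR's adjusted p was 0.0856 for PSAT1, 0.092 for SLC2A1, 0.164 for EPAS1 and 0.181 for NDRG1.

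Lists of secretion, lipid synthesis, chromatin and small RNA pathways held few called genes. Of 27 tested COPII and trafficking genes 1 fell, also when adjusted over the list alone, and it was SEC23A, with a list median of −0.03 and a camera adjusted p of 0.144. Of 29 tested cholesterol and fatty acid synthesis genes, 2 rose, also when adjusted over the list alone, the sterol reductase TM7SF2 1.49-fold and the fatty acid synthase FASN 1.28-fold, with a camera adjusted p of 0.415. Of 31 tested chromatin and polycomb genes 1 rose, also when adjusted over the list alone, the histone deacetylase HDAC9, 3.38-fold, from 1.71 ± 0.0582 to 5.79 ± 1.49 CPM. The chromatin list had a camera adjusted p of 0.142, which became 0.0262 without NC replicate 3. Of 22 tested small RNA pathway genes, 2 rose, or 3 adjusted over the list alone, and the list median was 0.10 with a camera adjusted p of 0.0159. That call was lost at an adjusted p = 0.401 with an estimated correlation, and camera gave 0.0534 without NC replicate 1 and 0.0682 without NC replicate 2. The genes that rose were TNRC6C, a silencing cofactor of Argonaute, 1.32-fold, and the Argonaute AGO4, 1.25-fold. AGO4 lost its edgeR call without each of the 6 libraries in turn, at an adjusted p of 0.178 without NC replicate 1, and with both other scalings, the stricter filter, DESeq2 and limma-voom. Without NC replicate 1, edgeR's adjusted p was 0.154 for TNRC6C, 0.0985 for FASN and 0.0524 for TM7SF2, and TNRC6C and FASN also lost their calls without mimic replicate 1. SEC23A overlaps an uncharacterised locus.

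**Figure D3:**
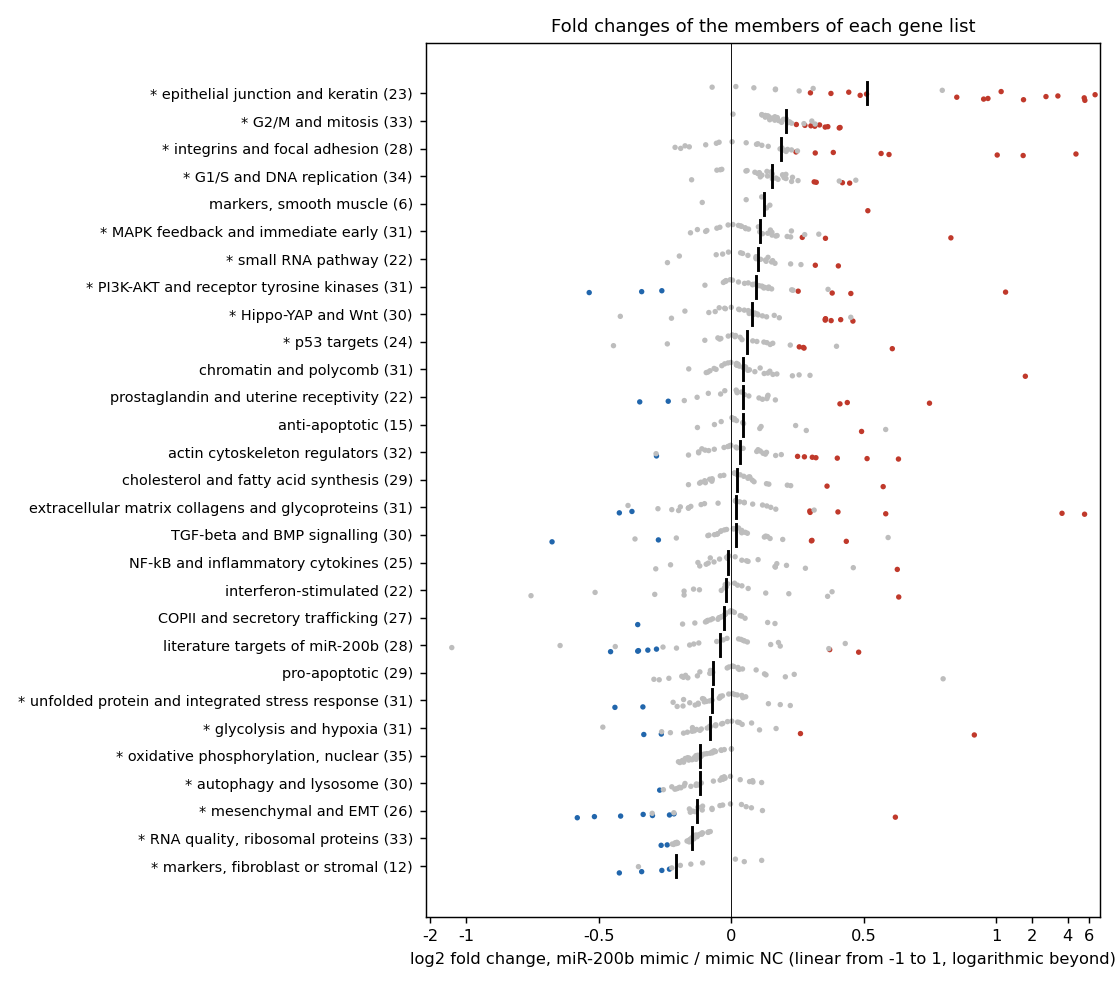
Log2 fold changes (mimic over NC) of the tested members of 29 gene lists, with 1 point per gene, red for called higher, blue for called lower and grey for the rest, and a black bar at each list median. Asterisks mark the 16 lists called by camera with its preset correlation, of which 9 were higher and 7 lower, and the axis is linear between −1 and 1 and logarithmic beyond. A split of the libraries that mixed the groups gave up to 14 such calls.

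Markers of other cell types were also measured. Of 12 tested fibroblast or stromal markers, 4 fell, none rose and 8 did not pass, and 5 were lower adjusted over the list alone. They were DCN, PDGFRB, PDGFRA and the matrix metalloproteinase MMP2, the last from 2213 ± 16.9 to 1882 ± 120 CPM. The stromal list had a median of −0.21 with a camera adjusted p of 0.00187, and an adjusted p = 0.401 with an estimated correlation. Some stromal markers were abundant in the NC libraries, COL1A2 at 11640 ± 402 and COL1A1 at 6622 ± 292 CPM, while THY1 stood at 5.35 ± 0.314. Among epithelial genes, the keratins KRT8 and KRT19 stood at 4494 ± 152 and 3917 ± 201 CPM in NC. CDH1 stood at 11.3 ± 0.912 and EPCAM at 0.0502 ± 0.0493 CPM in NC. The NC libraries thus held abundant transcripts of some genes of each kind, while others of each kind were scarce. Whether the same cells held both was not measured. Of 6 tested smooth muscle markers 1 rose, also when adjusted over the list alone, the actin nucleator LMOD1, 1.43-fold, with a camera adjusted p of 0.192. Endothelial, immune and glandular or ciliated markers had 4 tested genes each, too few for a list test. Of the endothelial markers, FLT1 rose while PECAM1 and the TGF-beta co-receptor ENG fell. The immune marker CD14 was lower, at 1.92 ± 0.203 against 3.13 ± 0.244 CPM, and none of the glandular or ciliated markers passed. ENG and CD14 were named after their values were seen. The edgeR adjusted p rose to 0.163 for PDGFRB, 0.229 for MMP2, 0.249 for FLT1 and 0.115 for PECAM1 without mimic replicate 2, to 0.173 for PDGFRA, 0.118 for ENG and 0.204 for CD14 without NC replicate 1, and to 0.0733 for LMOD1 without NC replicate 3. MMP2 lost its call when any library other than mimic replicate 1 was left out. FLT1, PDGFRA and CD14 each lost theirs without any of 4 libraries. CD14 also lost its call with DESeq2 and limma-voom, and FLT1 with these and with upper quartile scaling.

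Over-representation of the deposited annotation terms was tested with a one-sided Fisher's exact test against the tested genes that carry a term of that kind. This test takes genes as independent, so its p-values are too small where the genes of a term move together. Higher genes were over-represented in 29 of 2033 gene ontology terms and 25 of 297 KEGG pathways, and lower genes in 7 and 3. Focal adhesion held 27 higher genes of 151, where 7.25 were expected by chance, with an adjusted p of 4.47e-07 by Fisher's exact test. ITGB4, ITGA2, ITGA3 and THBS1 were among them. The same pathway held 12 lower genes, with 3.66 expected and a Fisher's exact adjusted p of 0.025. ECM-receptor interaction held 15 of 54 against 2.59 expected, and the tight junction pathway, with CRB3 and PATJ, held 19 of 118 against 5.67 expected. Lower genes were over-represented in the extracellular space term, with 33 of 386 against 8.21 expected and a Fisher's exact adjusted p of 1.33e-08, and they included GREM1, TNFRSF11B and VEGFA. The PI3K-Akt pathway held 25 higher genes, with 11 expected, and 18 lower genes, with 5.55 expected. Leaving out mimic replicate 3 raised the number of called terms from 64 to 101.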

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

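None of the alternatives in this part was chosen after the results were seen. The planned seed-site test and its alternatives were not run. Other scalings, filters, DESeq2 and limma-voom gave 491 to 622 higher and 259 to 341 lower genes, and 0 of the called genes changed sign under these, the replicate block or any left-out library. With the replicate block, 816 genes were higher, 496 lower and 105 terms called. The main test used no block, as planned, because the replicate numbers are not stated to pair the samples. Correlations of deviations between same-numbered libraries were −0.0515, 0.128 and 0.189. Mimic replicates 2 and 3 each correlated best with their own number, while mimic replicate 1 correlated better with NC replicate 2 (0.166). Whether the numbers mark something shared between the groups stays open. Under the block the p53 list was no longer called, at a camera adjusted p of 0.0548; the cause was not tested. Leaving out 1 library gave 275 to 731 higher genes, 82 to 414 lower genes and 46 to 101 terms. Fewer libraries are part of this, but removing mimic replicate 3 or NC replicate 2 raised the counts; the cause was not tested. The share of calls that were higher was 66.6% with all libraries and 79.7% without mimic replicate 2. A minimum log2 fold change of 1 left 101 higher and 13 lower genes, and an unadjusted p under 0.05 with that minimum 111 and 26, since the minimum admits fewer genes. An estimated correlation left 1 list and fry called 6, against 16 with the preset correlation. Fry called the epithelial, mesenchymal, integrin and p53 lists, and the actin and prostaglandin lists, which camera did not call. Among lists called by camera, fry gave an adjusted p of 0.126 for G2/M and 0.223 for G1/S. For oxidative phosphorylation it gave 0.13 and for ribosomal proteins 0.0952. For uncalled lists with medians near 0, the direction of the set test turned in some fits: without 1 library the TGF-beta list ranged from −0.0561 to 0.0487 and the interferon list from −0.0382 to 0.0196, and the interferon median stood at −0.0234 without a filter, −0.0189 under the stricter filter and −0.0193 under fry where the direction turned; the cause was not tested. Genes named only for their NC level are left out of the next counts. Of 121 tested genes named in the text 111 were called, of which 10 lost the call under another scaling, filter or tool, 47 without 1 library, and 0 changed sign. At this depth genes with few reads in both groups, such as BCL2, were not resolved.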

Other observations

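The tests of a foreign RNA source, of drift between libraries, of scaling and of level by the average of both groups were chosen, or their criteria changed, only after the results were seen.

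Genes of the classical complement pathway were lower with the mimic. C2 fell by 41.5%, from 100.1 ± 14.3 to 58.5 ± 10.8 CPM (SD, n = 3), C1R by 30% and C1S by 26.9%, and C4A, whose reads could be split among near-identical copies, by 40.5%. The more abundant C3 and CFB did not pass, with log2 fold changes of −0.21 ± 0.27 and −0.19 ± 0.16 and edgeR adjusted p of 0.78 and 0.64. The complement genes and the monocyte receptor CD14 were picked out after a called term, Pertussis, held 7 lower genes of 50 against 1.21 expected. C1S and CD14 lost their edgeR calls without mimic replicate 1, mimic replicate 2 or NC replicate 1, at an adjusted p of up to 0.0878 and 0.204. MYB, a transcription factor of proliferating progenitor cells also named after its values were seen, fell by 26.4%, with an edgeR adjusted p of 0.00065.

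For each result, 10 splits of the 6 libraries into 3 and 3 exist, so the share of splits as large as the real one cannot go under 0.1, whatever the effect. The real split called 525 higher and 263 lower genes and the highest other split 33 in a direction. The real split called 64 terms against 3, and 16 lists against 14, and in each case 1 split, the real one, reached the real value. The split with 14 lists, which grouped mimic replicates 1 and 2 with NC replicate 3, called 0 genes. The number of lists called under the preset correlation thus hardly set the real grouping apart.

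A group of 19 genes was nearly absent from the NC libraries, at 10% or less of the mimic level, and present in all 3 mimic libraries; they include CRB3, TNS4, EPHA1 and, chosen after their values were seen, MPZL2, KDF1 and SPINT1, the last of which overlaps a neighbour. RNA of a foreign epithelial source in the mimic libraries would keep these genes in 1 ratio. Their median spread over the mimic libraries was a chi-square per degree of freedom of 0.865. In 1000 random gene sets of like counts the median was 1.54 and the 95th percentile 2.47. Those sets were drawn only from genes far from the adjusted threshold, while the 19 genes had all passed it. That selection can itself favour an even spread. A response of the BEND cells to the mimic would keep the ratios too, so these explanations cannot be told apart by this test. Against a general epithelial source, 4 listed epithelial genes, CLDN4, PKP3, KRT5 and GRHL2, had 0 reads in all 6 libraries, which does not exclude a source that lacks them. Release of these genes from ZEB repression may be the biological cause, as ZEB1 was lower in all 3 mimic libraries than in any NC library, but this was not tested.

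The lower ribosomal protein genes and higher G2/M genes could reflect drift between libraries. The difference of the list means was 0.373 in the real split and at most 0.227 in the other splits, so 1 of 10 splits reached the real value, too few splits to decide. A trend on genomic span as the whole cause is argued against. After its removal the G2/M median was 0.192 ± 0.02 and the ribosomal protein median −0.139 ± 0.00675 (bootstrap SE), against 0.208 and −0.148 before. These SE come from resampling the genes of a list, not the libraries. Span had a Spearman correlation of 0.135 with fold change across 12164 genes, which are not independent. It is only a stand-in for transcript length, which was not measured, so a trend on transcript length stays open. An effect of the mimic on growth stays open and was not tested.

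Rises were larger than falls: 101 higher and 13 lower genes changed by at least 1 on the log2 scale. Other scalings moved the median of all genes by at most 0.00977, but each takes most genes as unchanged, so this does not test an offset between the groups and scaling stays open. A low level of the higher genes as the whole cause was tested by matching on level. The called genes were placed in 10 bins of the log-scale average of both groups, 8 of them informative. The common odds ratio of such a change, higher against lower genes, was 3.42 (95% interval 1.48 to 8.55, exact conditional p = 0.00169). It rested mainly on the second lowest bin, with 23 of 53 higher and 2 of 26 lower genes. The lowest bin had 62 of 70 and 8 of 9, and the third lowest 7 of 61 and 2 of 18. The exact test also takes genes as independent. The interval lay above 1, but the bins on either side of the second lowest had similar shares in both directions. No bin was tested alone, and the matched test was chosen after the results were seen. Whether a low level is the whole cause was thus not decided. In the planned test, 9 of 357 higher and 2 of 222 lower genes changed that much at an NC mean of 10 CPM or more (two-sided Fisher's exact p = 0.219). This met the criterion set in advance for a low starting level as a cause, a p of 0.05 or more. Under 10 CPM the counts were 92 of 168 against 11 of 41 (Fisher's exact p = 0.00158). The NC mean is part of the fold change, so the planned test was not taken to decide, a reading not set in advance. A low starting level as part of the cause stays open.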
